A study of Mus musculus with 2 samples.

How the data were processed

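MicroRNA libraries were analysed from the gastrocnemius, a calf muscle of mixed but mostly fast fibres, of 2 male B6CASTF1/J mice at 25 days of age. B6CASTF1/J is an F1 hybrid between an inbred laboratory strain and the wild-derived CAST strain. The labels number the libraries as biological replicates 1 and 2 of 1 group and name separate male animals, but they give both the same donor identifier, so the libraries may come from 1 animal. SDs and the spread between replicates would then be technical. The labels give an RNA size range below 30 for the libraries.

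The deposited values are raw read counts per miRNA gene, as whole numbers with no normalization. Reads were assigned to the mm10 genome with the GENCODE M21 annotation, per the deposited description of the files. The aligner, its version, adapter trimming and the handling of mismatches are not given in the sources used here. Each file held 3 count columns without a header, 4 summary rows and 2202 gene rows. From the values, the columns are counts without regard to strand, on the strand of the gene and on the opposite strand. All 2202 gene identifiers were found in GENCODE M21, from which symbols, mm10 coordinates, hairpin sequences and host genes were taken. Host genes were those on the same strand whose gene body held the hairpin.

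The column for the strand of the gene held the larger total in both libraries and was used, by a rule set before the data were examined. Its gene counts came to 1491341 in replicate 1 and 2028332 in replicate 2, and CPM values were computed on these totals. The summary rows were left out of library sizes and tests. Reads that aligned to several loci made up 69.8% of all reads in replicate 1 and 71.8% in replicate 2, unaligned reads 8.11% and 5.99%, and reads outside miRNA genes 2.21% and 1.64%. Gene counts made up 19.9% and 20.6%. Because reads that aligned to several loci are in no gene row, a miRNA whose sequence occurs at several loci is undercounted, and its gene rows hold only reads that could be placed at 1 locus. An annotated hairpin was marked as sharing sequence where any 20-base stretch of it, on either strand, occurred in another annotated miRNA gene. This held for 1107 genes, with 32.5% of counts in replicate 1 and 32.8% in replicate 2. Mature sequences and copies outside annotated miRNA genes were not used here. The strand column matters for 64 genes that overlap a miRNA gene on the opposite strand, which held 25.3% and 25.2% of counts, since the column without strand leaves reads in such overlaps unassigned. How reads from CAST alleles that differ from mm10 aligned was not analysed here.

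Differences between the libraries were tested per gene with an exact two-sided binomial test on the counts, conditional on their sum. Its expected share came from effective library sizes by TMM (edgeR 4.0.16, R 4.3.3). Benjamini-Hochberg adjustment ran over the 313 genes with at least 10 counts summed over both libraries, with a threshold of 0.05. This test compares 2 libraries with counting error only and says nothing of a condition. With 1 group there was no contrast for a quasi-likelihood test. Spread between the mice was estimated as the edgeR common dispersion with an intercept only, over genes with at least 10 counts in each library, and is given as the biological coefficient of variation (BCV). Correlations were computed across genes on log2(CPM + 1), over genes with at least 10 counts in at least 1 library. Log2 ratios give replicate 2 over replicate 1 after TMM. Intervals are exact 95% intervals (Clopper-Pearson). Intervals and floors cover counting error only, since PCR copies are not independent molecules. A count of 0 allows up to 3 counts, which is 2.01 CPM in replicate 1 and 1.48 CPM in replicate 2.

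Before the data were examined, 24 lists with 227 distinct miRNA symbols were fixed, covering muscle, other cell types that a muscle sample can hold, families and clusters, together with 12 pairs of genes from shared primary transcripts. Of these symbols, 6, among them Mir146a, were not among the gene rows under that name. Rows under a different name, such as Mir146, were not counted for them. The rule for naming genes took the 20 genes with the highest mean CPM and up to 4 members per list with the highest mean CPM. It also took both members of each pair and, among genes past the threshold with at least 100 counts in at least 1 library, the 5 largest and 5 smallest ratios. Other genes are named with a statement that they were chosen after their values were seen. For each list with enough members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

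The binomial step was tested on simulated counts of replicate 2 over replicate 1 with 200 changed genes. Among 316 genes in that step it recovered 28 of 39 genes changed 1.5-fold, 33 of 37 changed 2-fold and 35 of 39 changed 4-fold. It called 6 of 201 unchanged genes. The simulated counts held counting error only, with no spread between animals, so these rates do not carry over to the measured libraries. A simulated BCV of 20% was recovered as 21.8% over 265 genes. Alternatives covered DESeq2 1.42.0 size factors, totals without TMM, the column without strand, other count minimums and pseudocounts, thinned counts, a negative binomial test, totals without the highest gene and each library left out. The set of genes with an identical mature sequence could not be formed from the annotation, so genes sharing a 20-base stretch stood in for it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.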

Results

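MicroRNA abundance was measured in gastrocnemius muscle from 2 male B6CASTF1/J mice aged 25 days, with 1 library per mouse. The labels name separate animals but give both the same donor identifier, so that they are separate is not certain; from 1 animal, every SD and spread between the mice given here would be technical. Gene counts totalled 1491341 in replicate 1 and 2028332 in replicate 2. The design has 1 group. The data thus describe which miRNA genes had reads placed at 1 locus, at what level, and how far the animals differed. Values are means ± SD over the 2 mice (n = 2) unless stated otherwise. Of 2202 annotated miRNA genes, 267 had at least 10 counts in both libraries, 402 had at least 1 count in both and 1632 had none in either.

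A small set of miRNA genes made up most of the gene counts. These leave out the reads that aligned to several loci, 69.8% of all reads in replicate 1 and 71.8% in replicate 2. The order and shares below therefore hold for reads placed at 1 locus only. Mir378a, in an intron of Ppargc1b (chromosome 18, 61397835 to 61397900, minus strand), was the highest at 144533 ± 7598 CPM, or 14.5 ± 0.760% of gene counts. It was followed by the endothelial miRNA gene Mir126a in Egfl7 (chromosome 2, 26591357 to 26591429) at 82900 ± 6540 CPM. Mir23b (chromosome 13, 63300484 to 63300557) had 65130 ± 71.0 CPM, the smooth muscle miRNA gene Mir143 (chromosome 18, 61649196 to 61649258) 64179 ± 12850 CPM and Mir23a (chromosome 8, 84208518 to 84208592) 61898 ± 7397 CPM. Mirlet7g in an intron of Wdr82 had 58157 ± 5924 CPM and the muscle-specific Mir206 49955 ± 4826 CPM. Mirlet7i, Mir26b and the imprinted Mir127 completed the first 10 genes, with 44484 ± 1580, 37560 ± 1844 and 35988 ± 3408 CPM. The next 10 genes were Mir99a, Mir10b, Mir411, Mir30a, Mirlet7b, Mir22, Mirlet7d, Mir322, Mir335 and Mir21a, from 24757 ± 1824 down to 11739 ± 1194 CPM. The 10 highest genes held 64.5 ± 0.168% of counts, the 20 highest 81.2 ± 0.497% and the 50 highest 94.7 ± 0.0346%. In single libraries the 10 highest genes held 64.4% (exact 95% interval 64.3 to 64.4) and 64.6% (64.5 to 64.7). Mir378a and Mir126a overlap a miRNA gene on the opposite strand, and in the column without strand they fell to 0 and 0.330 CPM.

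The striated muscle list held 5.18 ± 0.472% of counts, nearly all of it from Mir206. Mir206 (chromosome 1, 20679010 to 20679082) had 79589 counts in replicate 1 and 94404 in replicate 2. Mir486, in an intron of Ank1, reached 750 ± 103 CPM, Mir499, in an intron of the slow myosin gene Myh7b, 435 ± 141 CPM and Mir1a-2 (chromosome 18, 10785481 to 10785552) 412 ± 42.8 CPM. Mir208b, in an intron of the slow myosin heavy chain gene Myh7, had 158 ± 93.8 CPM, whereas Mir208a, in the cardiac gene Myh6, had 5 and 9 counts. The 5 genes Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2 and Mir133b, a set chosen after their values were seen, held 0.0458 ± 0.00273% of counts together. Each of these 5 shares a 20-base stretch with another miRNA gene, and Mir133c, which does not, had no counts. Between the mice, 2 of 9 tested list members were higher in replicate 2 (Mir208b and Mir499), 3 were lower (Mir206, Mir486 and Mir1a-2) and 4 did not pass, with the same 2 and 3 adjusted over the list alone. The slow fibre and cardiac myosin-gene list, with 0.0596 ± 0.0236% of counts, had 2 of 3 members higher (2 adjusted over the list alone). Its median log2 ratio of 0.69 lay at the 98.3 percentile of random lists. Log2 ratios were 1.30 for Mir208b (exact 95% interval 1.03 to 1.59, binomial test adjusted p = 4.33e-22) and 0.69 for Mir499 (0.53 to 0.84, binomial test adjusted p = 1.96e-18). With the spread between the mice added to counting error, neither passed (adjusted p = 0.107 and 0.986, edgeR exact negative binomial test). That spread was estimated from the same 2 libraries and so includes the differences tested, which weighs against passing any gene. A gene that misses this test, here or in the values given later, is not shown to be alike in both mice.

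The list of miRNAs abundant in muscle and tied to metabolism held 26.7 ± 0.583% of counts, led by Mir378a, Mir23b, Mir26b and Mir22. Of its 13 tested members, 4 were higher in replicate 2, 3 were lower and 6 did not pass (4 and 3 adjusted over the list alone). Mir22, with 13963 ± 2940 CPM, had a log2 ratio of 0.44 and Mir378a of -0.10. The list total depended on Mir378a, and with that gene taken out of both sums it was 14.3%.

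The let-7 family held 14.4 ± 1.17% of counts and was lower in replicate 2. Of its 12 members, 10 were lower, 1 was higher and 1 did not pass, and 11 were lower and 1 higher adjusted over the list alone. Mirlet7g had a log2 ratio of -0.20, Mirlet7b of -0.35 and Mirlet7i of -0.06, while Mirlet7d stood at 0.06. The family median was -0.29, at the 0.06 percentile of random lists. Of the 12 members, 6 share a 20-base stretch with another miRNA gene, and the call for Mirlet7d ended when a linear trend with hairpin GC content was removed (binomial test adjusted p = 0.465). The miR-30 family, with 3.70 ± 0.266% of counts, went the other way: 4 of 6 members were higher in replicate 2 and none was lower (4 and 0 adjusted over the list alone). Mir30a, Mir30d, Mir30e and Mir30b had log2 ratios of 0.09, 0.17, 0.30 and 0.78. The miR-29 family held 0.135 ± 0.0461% of counts, and Mir29a and Mir29c were higher in replicate 2 at 0.69 and 0.88. Of its 4 members 2 were higher, and 2 were higher and 1 lower (Mir29b-1) adjusted over the list alone. Its median of 0.79 lay at the 99.1 percentile. With the spread between the mice, from the same 2 libraries, added, no member of these 3 families passed, with adjusted p = 0.694 for Mir29c, 0.940 for Mir30b and 1 for each let-7 member (edgeR exact negative binomial test). The group of miR-10, miR-99/100 and miR-125 genes held 6.82 ± 0.563%, with 5 of 8 members lower in replicate 2 and none higher (5 and 0 adjusted over the list alone), including Mir99a at -0.14, Mir10b at -0.13 and Mir100 at -0.24. Over these 4 families, the 13 members that share a 20-base stretch with another miRNA gene had a median of 208 CPM and the other 17 a median of 8439 CPM.

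**Figure D1:**
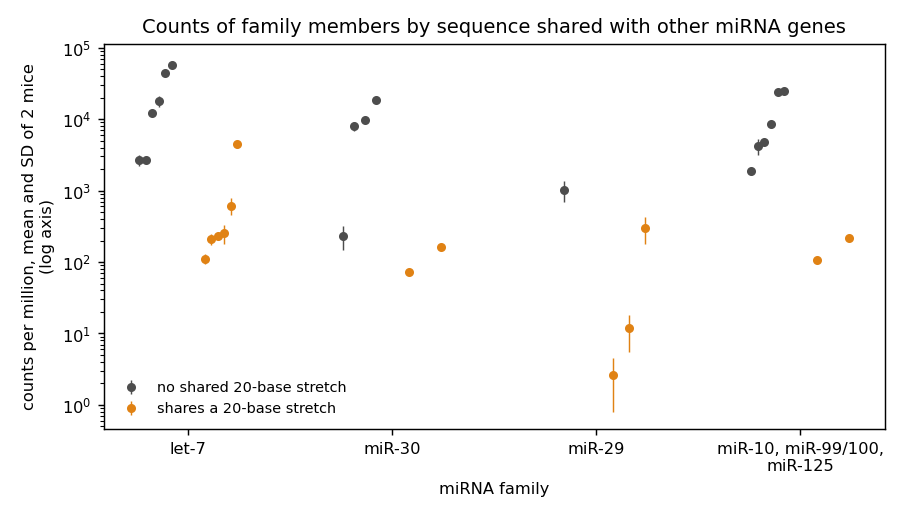
CPM (log axis) of each member of 4 miRNA families, as the mean and SD of 2 mice. Members that share a 20-base stretch with another annotated miRNA gene (orange, 13 genes, median 208) lie mostly below the other members (grey, 17 genes, median 8439).

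Genes of the Hox clusters, which mark position along the body axis, held 3.63 ± 0.315% of counts. Mir10b in Hoxd3 had 23772 ± 1584 CPM, Mir196b in Hoxa9 6093 ± 1454, Mir10a 4859 ± 60.5 and Mir196a-2 in Hoxc5 1415 ± 154. Of 6 tested members, 3 were lower in replicate 2 (Mir10b, Mir196b and Mir196a-2) and none higher (3 and 0 adjusted over the list alone).

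Lists of other cell types in muscle ranged from 8.29% of counts for endothelial to 0.204% for erythroid miRNAs. The endothelial list held 8.29 ± 0.654%, all but 1 count of it from Mir126a, which was higher in replicate 2 with a log2 ratio of 0.17 (1 of 1 tested, also adjusted over the list alone). The smooth muscle and pericyte list held 6.88 ± 1.40%, and both tested genes were higher in replicate 2 (2 adjusted over the list alone), Mir143 at 0.42 and Mir145a at 0.54. Fibroblast and connective tissue miRNAs held 2.47 ± 0.298%, led by Mir322 and Mir21a, with 3 of 7 higher (Mir322, Mir21a and Mir199b) and Mir214 lower in replicate 2 (3 and 1 adjusted over the list alone). Leukocyte miRNAs held 0.417 ± 0.0549%, without the gene row named Mir146, since the list gave the symbol Mir146a. Mir150, Mir155, Mir342 and Mir181b-2 were lower in replicate 2, Mir223 and Mir142 were higher and 3 of 9 did not pass (4 higher and 4 lower adjusted over the list alone). The erythroid list held 0.204 ± 0.0112%, with Mir451a, Mir144 and Mir15a higher and Mir16-1 and Mir16-2 lower among 6 tested (3 and 2 adjusted over the list alone). Mir15a led this list with 648 ± 143 CPM, then Mir16-1 with 603 ± 67.4 CPM. Mir451a and Mir144 had 212 ± 109 and 52.8 ± 18.7 CPM, so most of the erythroid share came from other genes. Mir451a, a red blood cell miRNA, had 201 and 587 counts and a log2 ratio of 1.11 (exact 95% interval 0.88 to 1.35, binomial test adjusted p = 2.53e-22), which did not pass with the spread between mice from the same 2 libraries added (adjusted p = 0.238, edgeR exact negative binomial test).

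The neuronal, epithelial, hepatic, pancreatic and pluripotency lists each held 0.163% of counts or less. The share of the neuronal list was not far below the 0.204% of the erythroid list. The neuronal list held 0.163 ± 0.00526%, most of it Mir128-1 at 1227 ± 47.9 CPM, and Mir137 was the 1 of 7 tested members higher in replicate 2 (1 adjusted over the list alone). Of its 17 measured members 14 share a 20-base stretch with another miRNA gene, among them all Mir9 and Mir124a genes (at most 1 count each), so reads of these that aligned to several loci are not in these counts. The epithelial and skin list held 0.0255 ± 0.00266%, led by Mir203 at 228 ± 21.6 CPM. Mir182, with 5 and 22 counts, was its 1 of 5 tested members higher in replicate 2, and 0 passed adjusted over the list alone. The hepatic miRNA gene Mir122 had 20 and 23 counts, and the pancreatic and enteroendocrine genes Mir375 and Mir217 had 8 counts each in replicate 1, and 7 and 8 in replicate 2. None of these 3 genes passed, over all genes or adjusted over the list alone. Pluripotency miRNAs were near the floor: 12 of 14 had no count, Mir302a had 1 and 2 counts and Mir302b 0 and 1, where a count of 0 allows up to 2.01 CPM in replicate 1 and 1.48 CPM in replicate 2. The hypoxia and immediate response list held 0.0454 ± 0.00289% (Mir132 188 ± 1.23 CPM, Mir34a 183 ± 22.0 CPM), with 0 of 4 tested members past the threshold, also adjusted over the list alone. The list linked to brown and white fat held 0.196 ± 0.0123%, with Mir193b higher and Mir196a-2 lower among 4 tested (1 and 1 adjusted over the list alone). MiRNAs of the proliferation-linked miR-17-92 and paralogous clusters held 0.430 ± 0.0164%, with Mir20a and Mir18 higher among 11 tested (2 and 0 adjusted over the list alone).

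**Figure D2:**
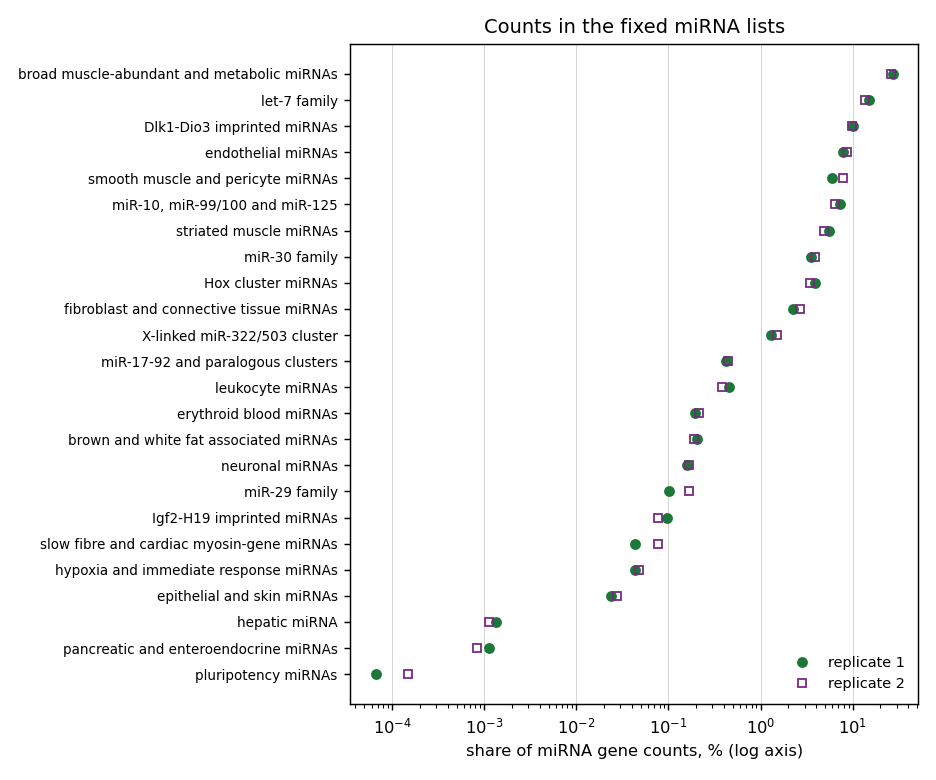
Share of miRNA gene counts (percent, log axis) in each of 24 miRNA lists, with 1 symbol per mouse. Shares run from 26.7% for miRNAs abundant in muscle to 0.000107% for pluripotency miRNAs (means of 2 mice).

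The imprinted Dlk1-Dio3 region on chromosome 12, whose miRNAs are transcribed from the maternal chromosome, held 9.91 ± 0.117% of counts. Of its 54 listed genes 50 had counts and 46 had at least 10 in both libraries, with a median of 273 CPM. Mir127 (109592846 to 109592915) led with 35988 ± 3408 CPM, then Mir411 (109710175 to 109710256) with 19662 ± 2266, Mir379 (109709060 to 109709125) with 9210 ± 446 and Mir487b with 7035 ± 231 CPM. The genes fell into a proximal block of 14 genes with 4.65 ± 0.303% of counts and a distal block of 40 genes with 5.26 ± 0.187%. Of 46 tested genes, 14 were higher in replicate 2, 9 were lower and 23 did not pass (15 and 9 adjusted over the list alone). The median log2 ratio was 0.01, at the 49.4 percentile of random lists. Mir136 had the largest ratio past the threshold in the region, with 181 and 586 counts and a log2 ratio of 1.26 (1.02 to 1.51), and Mir127 had -0.18. At the imprinted Igf2-H19 locus, Mir483 had 852 ± 138 CPM and Mir675, in the H19 transcript, 22.8 ± 2.90 CPM. Together they held 0.0874 ± 0.0140%, and Mir483 was lower in replicate 2 (1 of 2, also adjusted over the list alone). The X-linked cluster of Mir322 and Mir503 held 1.39 ± 0.148%. Mir322 was higher in replicate 2 at 0.32, Mir351 and Mir542 were lower at -0.58 and -0.28, and 4 of 7 did not pass (1 and 2 adjusted over the list alone).

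**Figure D3:**
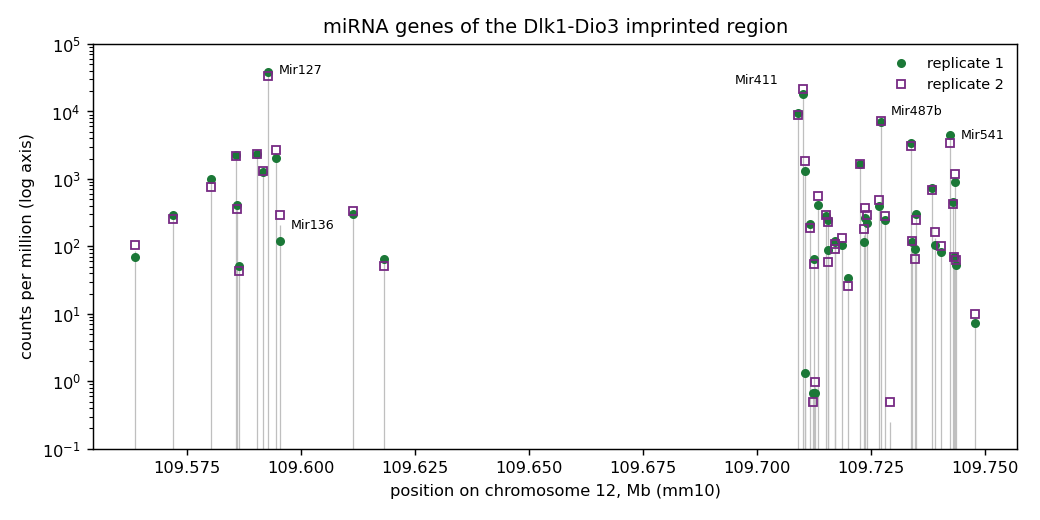
CPM (log axis) of Dlk1-Dio3 miRNA genes against their position on chromosome 12 (Mb, mm10), with 1 symbol per mouse and lines up to the mean. Values of 0 are not drawn. Mir127 leads the proximal block and Mir411 the distal block, at means of 35988 and 19662.

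In all 12 pairs, members of single primary transcripts had unequal counts. Counts of Mir206 exceeded those of its neighbour Mir133b by a mean log2 ratio of 11.64 ± 0.67, and Mir143 exceeded Mir145a by 3.81 ± 0.08. The ratio was -3.67 ± 0.16 for Mir27b over Mir23b, 1.95 ± 0.26 for Mir451a over Mir144 and -6.90 ± 0.15 for Mirlet7c-1 over Mir99a. Within the miR-30 and miR-29 transcripts it was 5.45 ± 0.43 for Mir30d over Mir30b, 6.77 ± 0.12 for Mir30e over Mir30c-1 and 6.97 ± 0.49 for Mir29c over Mir29b-2, the last gene having 2 and 8 counts. The remaining ratios were 5.28 ± 0.14 for Mir100 over Mir125b-1, 1.14 ± 0.19 for Mir99b over Mir125a, 4.82 ± 0.14 for Mir214 over Mir199a-2 and -2.27 ± 0.01 for Mir92-1 over Mir17. In 9 of 12 pairs the gene named first was over 2-fold higher in both mice. In the rest (Mir27b over Mir23b, Mirlet7c-1 over Mir99a and Mir92-1 over Mir17) it was over 2-fold lower in both. The median SD of the ratios was 0.16. No test was run, and a ratio that involves Mir133b, Mir23b, Mir27b, Mir29b-2, Mir29c, Mir30c-1, Mirlet7c-1, Mir125b-1, Mir199a-2 or Mir92-1 compares a gene that shares sequence with other loci. Where a single member of a pair shares sequence, that member had the lower counts in every case. Unequal output of the transcript cannot be told apart there from reads left out because they aligned to several loci.

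Across genes the mice were close. Over 289 genes Pearson's r of log2(CPM + 1) was 0.990 (bootstrap interval 0.987 to 0.992) and Spearman's rho 0.986, across genes that are not independent replicates. Of 179 genes with at least 100 counts in each library, 162 lay within 1.5-fold and 3 differed by over 2-fold. Beyond counting error, 62 of 313 tested genes were higher in replicate 2 and 58 were lower (exact binomial test, adjusted p under 0.05). Among genes past the threshold with at least 100 counts in a library, the largest ratios were those of Mir137 (log2 1.53, interval 0.98 to 2.14), Mir101a (1.40, 1.07 to 1.74), Mir208b, Mir136 and Mir451a. The smallest were those of Snord43 (-1.17, -1.55 to -0.81), Mir26a-2 (-0.82, -1.21 to -0.44), Mir224 (-0.64, -1.04 to -0.25), Mir342 (-0.64, -0.75 to -0.53) and Mirlet7a-1 (-0.61, -0.81 to -0.41). Snord43 carries the name of a small nucleolar RNA gene but is listed among the miRNA genes. A chi-square test of the counts gave 20979 on 312 degrees of freedom, more than the sampling noise of 1 library deposited in duplicate, though this does not show that the samples are independent. The BCV between the mice was 18.0% over 267 genes (bootstrap interval 16.1 to 20.1). With that spread added, 0 of 313 genes passed and 15 had an unadjusted p under 0.05 (edgeR exact negative binomial test, smallest adjusted p = 0.107). Taking the spread from the same 2 libraries scales the test to their differences and weighs against passing any gene. An unadjusted p under 0.05 is then met by roughly that fraction of genes, however far the libraries differ. The 15 and the 0 are thus no measure of how far the mice differ. How strongly single genes are affected was not tested. Percentiles among random lists were computed for 18 of the 24 lists. Besides those given above, they were 91.8 for striated muscle, 46.2 for muscle-abundant, 78.9 for miR-30, 13.3 for miR-10, miR-99/100 and miR-125, 6.12 for Hox, 76.7 for erythroid, 91.0 for leukocyte and 69.2 for fibroblast miRNAs. They were 19.5 for neuronal, 57.8 for epithelial, 21.5 for fat, 85.7 for miR-17-92 and 55.9 for hypoxia miRNAs, and 49.0 for the X-linked cluster.

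**Figure D4:**
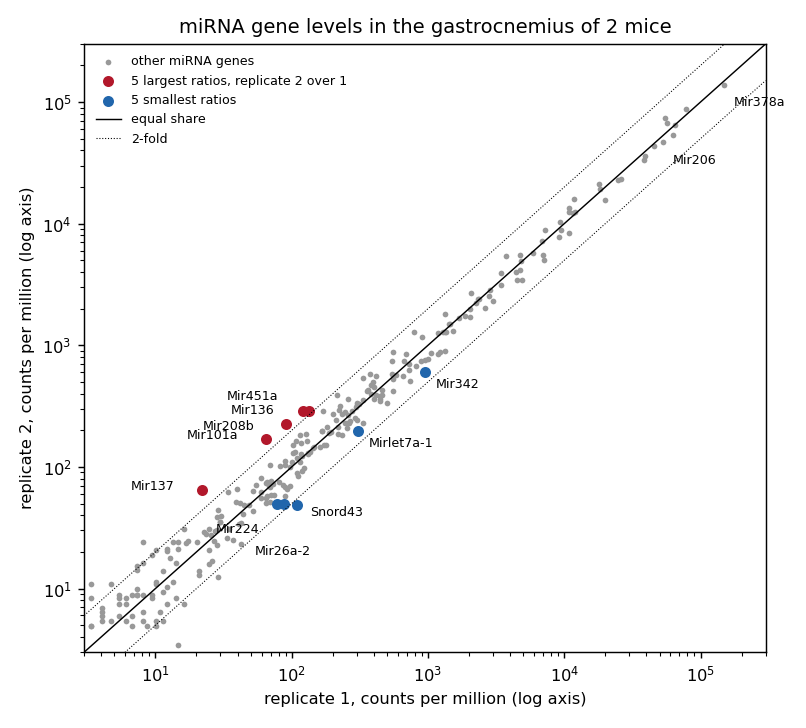
CPM of 285 miRNA genes in replicate 1 (x) and replicate 2 (y), both on log axes; 4 genes below 3 CPM in a library lie outside the axes. Coloured points are the 5 largest (red) and 5 smallest (blue) ratios past the threshold with at least 100 counts in a library, and dotted lines mark 2-fold differences.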

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

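Both tests of the low Mir1a and Mir133a counts given here were chosen after those counts had been seen.

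Counts on the strand opposite to the gene are not part of the values reported above. Summed over all genes that overlap no other miRNA gene, they came to 22 in replicate 1 and 22 in replicate 2. These sums equal 0.00148% and 0.00108% of gene counts. The genes with the most were Mir122 with 6 and 2 counts, Mir708 with 4 and 4 and Mir200a with 2 and 4, named after their values were seen. Reads that aligned to several loci, 5227800 in replicate 1 and 7067363 in replicate 2, enter no gene row and are likewise outside the values reported above.

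Mir1a and Mir133a are abundant in skeletal muscle in general knowledge, yet their genes had few counts here beside Mir206. A candidate explanation is that their reads align to several loci and so reached no gene row. In the let-7, miR-30, miR-29 and miR-10, miR-99/100 and miR-125 families, members that share a 20-base stretch had a median log2(CPM + 1) different from the others by -5.34 (permutation test within families, one-sided, p = 0.00011), which is in line with it. This difference holds for those families only. Elsewhere, Mir378a, Mir23b and Mir23a also share a stretch and had means of 144533, 65130 and 61898 CPM, named after their values were seen. All 1107 genes that share a stretch held 32.5% of counts in replicate 1 and 32.8% in replicate 2. A shared stretch thus does not by itself mean low counts. Too little room in the reads left out was argued against. There were 65.7 such reads per Mir206 count in replicate 1 and 74.9 in replicate 2. The deposited values do not say which loci those reads came from, so how many of them belong to Mir1a or Mir133a stays open, and no biological explanation was tested.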

How the results depend on the processing

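Removing a GC trend (fitted over all genes or without those sharing a stretch), leaving out genes that share a 20-base stretch from the tests and BCV, and thinning replicate 2 alone were chosen after seeing the data. No paired analysis was possible because there is 1 group. The number of genes differing between the libraries (120) was 110 to 130 under every alternative but 2. It was 93 with genes sharing a stretch left out, of fewer tested, and 0 in the negative binomial test. The latter adds the spread between the mice by construction and takes it from the same 2 libraries, which weighs against passing any gene. The BCV was 16.5 to 18.3% and the number of genes with enough counts 179 to 300. The correlation rose to 0.993 over all genes. These include 1632 genes with no count in either library, whose equal values raise r by construction. The effect of the other added genes was not tested. The share of the 10 highest genes was 62.3% without strand and 65.4% without genes sharing a stretch. Values with 1 library left out stay within 1 SD by construction and say nothing on stability.

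In the column without strand, reads in overlapping genes are unassigned and the total is smaller. Shares fell where such genes led the list (endothelial and muscle-abundant) and rose for the other lists given here, including several that also lost overlapped members, such as striated muscle, let-7 and Dlk1-Dio3. Shares were 6.77% for striated muscle, 16.4% for muscle-abundant, 18.9% for let-7, 9.12% for miR-10, miR-99/100 and miR-125, 4.86% for Hox, 0.245% for erythroid, 0.527% for leukocyte, 3.30e-05% for endothelial, 9.20% for smooth muscle, 3.30% for fibroblast, 0.218% for neuronal, 0.0345% for epithelial, 0.00199% for hepatic, 0.00126% for pancreatic, 0.262% for fat, 0.575% for miR-17-92, 12.6% for Dlk1-Dio3, 0.117% for Igf2-H19, 0.0608% for hypoxia and 1.86% for the X-linked cluster. With Mir378a out of the total, other shares rise by construction: 6.05% for striated muscle, 14.3% for muscle-abundant (which loses Mir378a), 16.8% for let-7, 4.33% for miR-30, 7.97% for miR-10, miR-99/100 and miR-125, 4.25% for Hox, 0.238% for erythroid, 0.488% for leukocyte, 9.69% for endothelial, 2.88% for fibroblast, 0.190% for neuronal, 0.0298% for epithelial, 0.00145% for hepatic, 0.229% for fat, 0.502% for miR-17-92, 11.6% for Dlk1-Dio3, 0.102% for Igf2-H19, 0.0531% for hypoxia and 1.63% for the X-linked cluster. The remaining lists moved by less than 1 SD.

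Ratios of named genes kept their direction and side of the threshold with DESeq2 size factors and with totals alone (92 each). Removing the GC trend ended 2 calls, Mirlet7d and Mir335, and added 1, Mir29b-1. The column without strand added 4 calls, Mir23b, Mir10a, Mir128-1 and Mir34a, gave no ratio for 7 called genes, Mir378a, Mir126a, Mir30e, Mir451a, Mir136, Mir486 and Mir1a-2, and gave no value for the pairs Mir451a with Mir144 and Mir30e with Mir30c-1. Depth limits genes near 2.01 CPM in replicate 1 and 1.48 CPM in replicate 2.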

Other observations

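The trend and thinning tests were written down before their statistics were computed, but after the ratios of single genes had been seen, and the corrections they use were added after the data were examined.

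Several abundant miRNA genes lay outside the fixed lists and are named here after their values were seen. Besides Mir23a and Mir335, the latter in an intron of the imprinted gene Mest, these were Mir139 at 9596 ± 1810 CPM, Mir191 at 6214 ± 1045, Mir151 in an intron of Ptk2 at 5788 ± 136, Mir744 in an intron of Map2k4 at 4216 ± 273 and Mir140 in Wwp2 at 3687 ± 340 CPM (SD, n = 2). By host gene, hairpins in introns of protein-coding genes held 40.7 ± 2.06% of counts, intergenic hairpins 31.5 ± 2.23%, hairpins in exons of protein-coding genes 12.8 ± 0.986%, in exons of non-coding genes 10.8 ± 0.799% and in introns of non-coding genes 4.14 ± 0.350%.

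The 2 libraries differed at 120 genes beyond counting error in the binomial test. That test cannot tell a difference between animals from a difference between library preparations. It already takes the lower depth of replicate 1 into account through the library sizes. Thinning replicate 2 to that depth could thus change the calls only through lost counts, and cannot decide on depth as a cause. After thinning, 110 genes passed, 106 of them the same genes. A linear trend with hairpin GC content as the whole cause was argued against, since 126 passed after its removal. A GC contribution stays open: Spearman's rho between log2 ratio and hairpin GC was -0.134 across 179 genes (95% interval by Fisher's transformation -0.284 to 0.0215, permutation test, two-sided, p = 0.0735). The bound written beforehand against this trend, a rho within 0.2 of 0 with p of 0.05 or more, was met, but it was set aside after rho was seen because the interval includes values beyond -0.2. Over the 132 of these genes that share no 20-base stretch, rho was -0.227 (-0.391 to -0.0477, permutation test, two-sided, p = 0.00978), past the size set beforehand for a trend, and 130 genes passed after removing the trend fitted to them, a test chosen after the data were seen. The hairpin stands in for the sequenced arm, which is not given, and no biological explanation was tested with 1 group.

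Mir208b and Mir499, both in slow myosin genes, had higher shares in replicate 2. Genes linked to other cell types passed in both directions, also within single lists. Leukocyte genes Mir223 and Mir142 were higher, and Mir150, Mir155, Mir342 and Mir181b-2 lower. Of the erythroid list, Mir451a, Mir144 and Mir15a were higher and Mir16-1 and Mir16-2 lower. Of the fibroblast list, Mir322, Mir21a and Mir199b were higher and Mir214 lower. Mir145a, Mir143 and Mir126a were higher. The median log2 ratio of Mir208b and Mir499 was 0.99 before removal of the linear GC trend and 0.97 after (bootstrap SD of the trend 0.03). It was 0.94 with the trend fitted without genes that share a stretch. Removal could hardly lower these ratios, since the slope over all genes was -0.06 per 10 percentage points of GC. The hairpins have 45.5% GC (Mir208b) and 51.9% (Mir499). The fitted linear trend was thus small at these genes, and its removal cannot decide on GC content as a cause. Spread between samples stays open, since its only estimate, the BCV, comes from the differences between the same 2 libraries. No biological explanation was tested.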
